A study of Homo sapiens with 6 samples.

How the data were processed

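The series holds 6 RNA-seq samples of BE(2)-C cells, 3 transfected with a scrambled siRNA and 3 with an siRNA against PCIF1, all treated with ATRA. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and made into poly(A)-selected, strand-specific Illumina libraries, and the ATRA medium was changed every 24 h. The submitters' processing notes name bcl2fastq 2.20, cutadapt 3.7, STAR 2.7.10a, HTSeq, deepTools, DESeq2 and the hg38 build, without the role or settings of each. The gene annotation and the strand setting used for counting are not given in the sources used here.

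One table was analysed, the authors' deposited DESeq2 comparison, per the file headers with 6 columns for each of 13885 genes. The authors' first column is the mean of normalised counts over all samples, a signal that is never negative. Their log2 fold change and its SE are log2 values deposited by the authors. The authors' Wald statistic is a score with no fixed range. The p-value and the adjusted p-value are as the authors deposited them; adjusted values equalled a Benjamini-Hochberg adjustment over exactly the listed genes, and p-values the two-sided normal tail of the statistic. No values per library were analysed here, so every printed value is that of the authors' comparison, with its SE as the measure of spread. Depth per library is unknown, and precision is read from the SE, which ran from 0.12 to 0.30 with a median of 0.18. The SE never exceeded 0.295 and the ratio of fold change to SE departed from the Wald statistic by up to 2.16, as happens when fold changes are shrunken towards 0 under a normal prior; the header does not state it. Printed fold changes may for that reason understate changes, also large ones of well-expressed genes. Under that reading the unshrunken values in the authors' deposited table were estimated as -0.93 for PCIF1, -4.13 for HMOX1 (5.73% of the siScramble level in place of 7.70%) and 2.96 for FAM160A1.

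The direction was set as siPCIF1 over siScramble from the sign of PCIF1, against the plain order of the groups in the name of the table. Gene symbols, coordinates, transcript sequences, GC content and 3′ UTRs came from GENCODE 29 on GRCh38, matched on the identifier without its version; 13877 of 13885 identifiers matched, 13271 with the same version. The main transcript of a gene was the one ranked best by APPRIS, then by the basic tag, transcript support level and length. Lists of 28 groups of genes, the rule for named genes and the tests were fixed before the data were examined. The scan of 3′ UTR words was not among those tests, nor were the additions named below. Named genes were PCIF1, PCF11, the 12 largest increases and 12 largest decreases with an adjusted p under 0.05, a mean of at least 100 and a symbol that is not a clone or locus name, and up to 4 members of each list by smallest adjusted p, plus members needed to give the counts. Values of 2 genes taken by this rule are not reported here. Further members and regulators named in the text were chosen after their values were seen.

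Genes with a DESeq2 adjusted p under 0.05 in the authors' deposited table were counted as changed. The 28 lists and the family of zinc finger genes were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset inter-gene correlation of 0.01, two-sided, and a Benjamini-Hochberg adjustment over the 29 lists. Counts of members were also made with p-values adjusted over the list alone. Length and GC content were compared by Spearman's correlation across genes with a mean of at least 100, and medians in 5 bins were given bootstrap intervals. First bases were compared by a permutation test with 100000 resamples. All 7-base words in the 3′ UTRs of 8052 genes were tested for a relation to the log2 fold change by linear regression, with UTR length, UTR and transcript GC content, gene length and mean expression as covariates. For base composition, genes were split at random into 2 sets; the lowest word of each set was ranked in the other among the words of the same bases. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

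The steps were tested on simulated data. For this comparison, with 13885 genes and the deposited SEs, 92.0% of 200 genes shifted by 1 on the log2 scale were called with the right sign, and 6.12% of calls were on unshifted genes. Of the shifted lists with at least 5 measured members 87.5% were called, and 0 of the unshifted ones by cameraPR. A word given a shift of -0.15 in 8052 genes ranked 1 from the lowest. The simulated genes were independent of each other. In the simulation of single genes, the unshifted genes had only the spread of the deposited SEs. The Wald statistics of the authors' deposited table were wider, with a robust SD of 2.44. The simulations therefore check the steps and give no error rate for the data.

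Alternatives were other thresholds, a minimum fold change, a test against an absolute log2 change of 0.3, a minimum mean of 100, centring, an empirical null, a correlation of 0.05, ranks and 10000 random lists matched on mean expression, and other definitions of length and first base. Removal of the trend with GC content, length and expression, leaving out genes with TCAAGT in the main transcript, the unshrunken value of PCIF1 and partial correlations given GC content were added after the data were seen.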

Results

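RNA was measured in BE(2)-C cells, a human neuroblastoma cell line with amplified MYCN that takes on a more neuronal form in retinoic acid. The 6 samples fall into 2 groups of 3. One group had received a small interfering RNA against PCIF1 and the other a scrambled control, for 24 h in both cases. All 6 samples were then kept in 10 µM all-trans retinoic acid (ATRA) for 4 days. PCIF1 is the methyltransferase that makes m6Am, a methylated form of adenosine placed next to the mRNA cap. PCF11, named in the series title, is a factor of mRNA 3′ end cleavage and transcription termination. The values are those of the authors' deposited table, a DESeq2 comparison of the 2 groups with 13885 genes. Its mean normalised counts ran from 7.01 to 4.78e+06 per gene with a median of 175, and summed to 1.41e+07. The total count of each library is not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples.

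PCIF1, the siRNA target, differed between the groups, and its change was read as a decrease with siPCIF1. The authors' deposited table gave it a log2 fold change of -0.82 (SE 0.19) at a mean normalised count of 167, with a DESeq2 adjusted p of 0.000167. That change in the authors' deposited table corresponds to 56.6% of the siScramble level, with a 95% interval of 43.7 to 73.4% from its SE. The main transcript of PCIF1 has a GC content of 60.3%, and GC-rich genes tended to be lower. With the trend with GC content, length and expression removed, PCIF1 was at -0.58 in the authors' deposited table. Its adjusted p from the DESeq2 values was then 0.0137. PCIF1 (ENSG00000100982.11) lies on chromosome 20 from 45934628 to 45948023 in GRCh38. The direction of every fold change below, siPCIF1 over siScramble, was taken from PCIF1 itself, because the header of the table does not state it, so the sign of PCIF1 is no evidence that the siRNA worked. The name of the table puts siScramble before siPCIF1, which read plainly would give the opposite direction, and with that reading every sign would turn. PCF11 (ENSG00000165494.11; chromosome 11, 83156988 to 83187451) was at 0.35 (SE 0.16) in the authors' deposited table and did not pass, with a DESeq2 adjusted p of 0.0667. After the fold changes were centred on their median, which lay at -0.02 in the authors' deposited table, the adjusted p of PCF11 from the DESeq2 values was 0.0484. Among genes with a mean of at least 100 it was 0.0567. With the trend with GC content, length and expression removed, PCF11 was at 0.16 in the authors' deposited table, with an adjusted p from the DESeq2 values of 0.494.

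Many genes differed between the groups. In the authors' deposited table, 4716 of the 13885 genes passed a DESeq2 adjusted p of 0.05, of which 2263 rose and 2453 fell. With the trend with GC content, length and expression removed from the authors' deposited table, 3485 of 13877 genes passed, 1716 higher and 1769 lower. Part of the 4716 therefore followed that trend, whose source was not tested. Decreases made up 52.0% of the changed genes in the authors' deposited table (95% Clopper-Pearson interval 50.6 to 53.4%, which treats genes as independent), and 47.9% after centring and 62.7% of those without TCAAGT in the main transcript. Genes without TCAAGT were not matched on length or GC content, and short genes and GC-rich genes fell more often than others. Large changes were fewer and more often decreases, with 282 increases and 449 decreases of at least 1 on the log2 scale in the authors' deposited table. These splits rest on the direction taken from PCIF1. Read in the plain order of the table's name, increases and decreases would trade places, and large changes would more often be increases.

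HMOX1, the inducible heme oxygenase, had the largest decrease among the named genes. Its log2 fold change in the authors' deposited table was -3.70 (SE 0.19), or 13.0-fold lower (-4.13 when estimated without shrinkage), with a DESeq2 adjusted p of 8.49e-78 (ENSG00000100292.16; chromosome 22, 35380361 to 35394214). Its 3′ UTR holds TCAAGTA; for the 1297 genes with TCAAGTA or ATCAAGT there, against genes without TCAAGT, the coefficient on the log2 fold change of the authors' deposited table was -0.14 (SE 0.016) with GC content, length and expression as covariates. Without covariates these genes were not lower: the medians in the authors' deposited table were 0.05 with ATCAAGTA and 0.12 with either 7-base word alone, against -0.07 with no site. Among the next largest decreases of the authors' deposited table were WIPI1, a phosphoinositide-binding protein of autophagosome formation, at -2.46 (SE 0.18), and ARG2, the mitochondrial arginase, at -2.36 (SE 0.18). The authors' deposited table placed the endoplasmic reticulum proteins CRELD2, SDF2L1 and HYOU1 at -2.37 (SE 0.15), -2.33 (SE 0.17) and -2.18 (SE 0.14). CDC20, the mitotic activator of the anaphase-promoting complex, was at -2.33 (SE 0.16) and the transcription factor MYC at -2.22 (SE 0.19) in the authors' deposited table. FLNC, which encodes filamin C, INHBE, which encodes an inhibin subunit, and TNFRSF10B, a death receptor, were at -2.14 (SE 0.17), -2.13 (SE 0.21) and -2.13 (SE 0.16) in the authors' deposited table. The 55-base locus annotated as MIR3929 (chromosome 18, 35934088 to 35934142) was at -2.49 (SE 0.20) in the authors' deposited table; reads there do not measure a mature microRNA in this kind of library, and its value is uncertain.

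FAM160A1 showed the largest increase by the same rule, at 2.67 (SE 0.21) or 6.37-fold in the authors' deposited table, with a DESeq2 adjusted p of 2.61e-32 (ENSG00000164142.15; chromosome 4, 151409216 to 151663632). Some of the other increases encode neuropeptides or a neuronal receptor. The neuropeptide precursor CARTPT was at 2.09 (SE 0.19) and CRH, which encodes corticotropin-releasing hormone, at 1.59 (SE 0.14) in the authors' deposited table. UNC5A, a netrin receptor, was at 1.54 (SE 0.19) in the authors' deposited table. INSRR, an insulin receptor relative, was at 2.05 (SE 0.21) in the authors' deposited table. Further increases in the authors' deposited table were DNAJC22 at 2.05, the cationic amino acid transporter SLC7A2 at 1.84, CD177 at 1.76, riboflavin kinase RFK at 1.56, LRRC58 at 1.55 and the plasma membrane calcium pump ATP2B4 at 1.51, each with an SE of 0.15 to 0.20. PCF11, INSRR, WIPI1, CRELD2, ARG2 and TNFRSF10B overlap a gene on the opposite strand, PCF11 also 1 on its own strand, and the strand setting of the counting is not given in the sources used here.

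**Figure D1:**
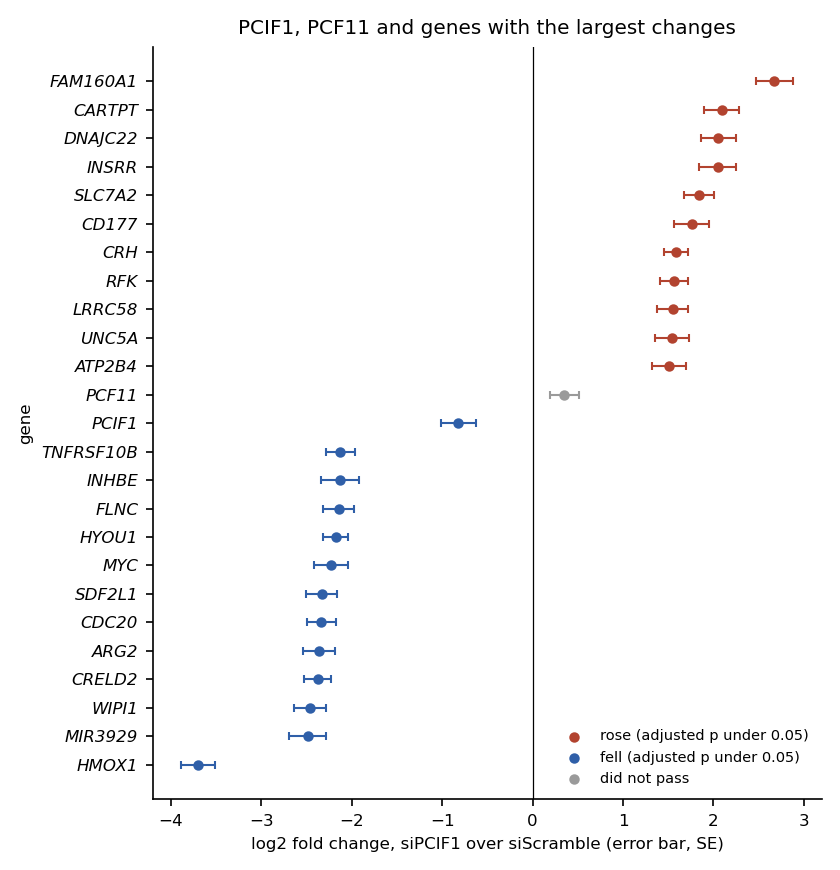
Log2 fold change, siPCIF1 over siScramble, of PCIF1, PCF11 and 23 genes with the largest changes in the authors' deposited table (points; error bars, SE; red rose, blue fell, grey did not pass). HMOX1 stands lowest at -3.70 and FAM160A1 highest at 2.67, with PCIF1 at -0.82 and PCF11 at 0.35.

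These counts depend on how the null spread is set. The Wald statistics of the authors' deposited table had a robust SD of 2.44, which real changes also widen; scaled to that SD, 135 genes passed (21 higher, 114 lower) and PCIF1 did not, at an adjusted p of 0.747 from the rescaled DESeq2 statistics. With a DESeq2-based test against an absolute log2 change of 0.3, 1526 genes passed from the authors' deposited table.

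Genes of the endoplasmic reticulum folding machinery fell almost together. Of 20 measured endoplasmic reticulum chaperones and related genes, 19 fell and 0 rose in the authors' deposited table at a DESeq2 adjusted p of 0.05 (20 fell when adjusted over the list alone; 5998 genes of the table had an unadjusted p under 0.05), with a median log2 fold change of -1.54. HYOU1, PDIA4, CALR and the main luminal chaperone HSPA5 were at -2.18, -2.12, -1.80 and -1.81 in the authors' deposited table, with SEs of 0.14 to 0.20. CANX, which encodes the membrane chaperone calnexin, was the exception at -0.26 (SE 0.13, DESeq2 adjusted p = 0.107) in the authors' deposited table. Against all other genes the list was lower with a cameraPR adjusted p of 2.87e-46.

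The integrated stress response genes, transcribed in large part through ATF4, fell as well. Of 23 measured members, 22 fell in the authors' deposited table and 0 rose by DESeq2 (22 fell and 1 rose when adjusted over the list alone), with a median of -1.11. SHMT2, an enzyme of mitochondrial one-carbon metabolism, was at -2.04 (SE 0.15), the amino acid transporter subunit SLC3A2 at -1.55 (SE 0.16), DDIT3 at -1.63 (SE 0.18) and ATF4 itself at -1.28 (SE 0.15) in the authors' deposited table. VLDLR was the member that did not fall, at 0.33 (SE 0.14, DESeq2 adjusted p = 0.0627) in the authors' deposited table. The cameraPR adjusted p of the list was 7.33e-24.

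Mitosis genes were lower, whereas more DNA replication genes rose than fell. Of 25 measured mitosis genes, 19 fell and 0 rose in the authors' deposited table by DESeq2 (20 fell when adjusted over the list alone), with a median of -1.02 and a cameraPR adjusted p of 4.28e-22. CDC20, the kinesin KIF2C, cyclin B1 (CCNB1) and the ubiquitin-conjugating enzyme UBE2C were at -2.33, -1.94, -1.93 and -1.75 in the authors' deposited table, with SEs of 0.14 to 0.16. MKI67, TOP2A, CDK1, KIF11, NDC80 and BUB1B were at -0.14, -0.19, -0.29, 0.16, -0.15 and -0.35 in the authors' deposited table and did not pass. Of the 11 members without TCAAGT in the main transcript in each of the chaperone, stress response and mitosis lists, 10, 11 and 11 fell in the authors' deposited table by DESeq2. Among DNA replication genes 17 of 34 rose and 2 fell in the authors' deposited table by DESeq2 (19 and 3 when adjusted over the list alone), with a median of 0.40 and a cameraPR adjusted p of 0.00033. The replicative helicase genes MCM6 and MCM4 and the sliding clamp PCNA were at 1.17 (SE 0.18), 0.84 (SE 0.13) and 0.84 (SE 0.15), and TYMS and CDC6, the members that fell, at -0.45 and -0.41 in the authors' deposited table. Among 20 replication-dependent histone genes, 11 fell and 0 rose in the authors' deposited table by DESeq2 (12 fell when adjusted over the list alone), with a median of -0.44 and a cameraPR adjusted p of 0.00196. With the trend of GC content, length and expression removed from the authors' deposited table, their median was -0.11, with 2 genes passing as lower and 2 as higher. The usual form of those mRNAs ends in a stem-loop without a poly(A) tail. Which form these poly(A)-selected libraries held is not known. Small nucleolar RNAs, which lack a long poly(A) tail, had a median of -0.47 in the authors' deposited table, and of -0.21 with the trend removed.

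More ribosome biogenesis genes rose than fell, and more cytosolic ribosomal protein genes fell than rose. Of 29 measured ribosome biogenesis genes, 14 rose and 1 fell in the authors' deposited table by DESeq2 (the same counts adjusted over the list alone), with a median of 0.42 and a cameraPR adjusted p of 0.000103. The nucleolar proteins NOLC1, UTP20 and DDX21 were at 1.04, 0.96 and 0.85, and RRP12, the member that fell, at -0.41 in the authors' deposited table. Of 77 cytosolic ribosomal protein genes, 29 fell and 0 rose in the authors' deposited table by DESeq2, also when adjusted over the list alone, with a median of -0.27 that became 0.0021 once the trend with GC content, length and expression was removed. RPL10A, at -0.71, and RPL10, at -0.62, had the smallest adjusted p of that list in the authors' deposited table. The cameraPR adjusted p of the ribosomal protein list was 0.000373, and 0.0677 with a preset inter-gene correlation of 0.05.

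Factors of mRNA 3′ end formation and of cap and adenosine methylation tended upward. Of 28 cleavage and polyadenylation factors, 9 rose and 0 fell in the authors' deposited table by DESeq2, also when adjusted over the list alone, with a median of 0.28. RPRD1A, CSTF3, CPSF3 and CPSF2 were at 0.71 (SE 0.17), 0.76 (SE 0.19), 0.56 (SE 0.15) and 0.59 (SE 0.16) in the authors' deposited table. The list had a cameraPR adjusted p of 0.0208, and 0.13 with a preset correlation of 0.05. Of 32 measured genes of the cap and adenosine methylation machinery, 12 rose and 2 fell in the authors' deposited table by DESeq2 (14 and 2 when adjusted over the list alone), PCIF1 being one that fell and the demethylase gene ALKBH5, at -0.39, the other. The cap-binding protein NCBP2 was at 1.01 (SE 0.16), ZC3H13 at 0.68 (SE 0.17) and the reader YTHDF3 at 0.58 (SE 0.15) in the authors' deposited table. For this list the cameraPR adjusted p was 0.00667, and 0.081 with a preset correlation of 0.05. Integrator and elongation factors went both ways, with 10 of 34 up and 5 down in the authors' deposited table by DESeq2 (10 and 6 when adjusted over the list alone); LEO1 was at 1.26 and INTS3 at -0.63, and the cameraPR adjusted p was 0.544. Among 12 genes of the RNA interference machinery, 4 rose and 1 fell in the authors' deposited table by DESeq2, also when adjusted over the list alone, with DICER1 at 0.89 and XPO5 at -0.81 (cameraPR adjusted p = 0.129).

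Retinoic acid response genes changed in both directions in cells that all received ATRA. Of 20 measured members, 7 rose and 4 fell in the authors' deposited table by DESeq2 (8 and 4 when adjusted over the list alone), with a cameraPR adjusted p of 0.055. The retinoic acid hydroxylase genes CYP26B1 and CYP26A1 were at 1.33 (SE 0.18) and 1.13 (SE 0.17) and the transglutaminase TGM2 at -1.42 (SE 0.17) in the authors' deposited table. Of 13 measured HOX genes, 2 rose in the authors' deposited table by DESeq2, HOXC6 at 0.47 and HOXD9 at 0.46, and 0 passed when adjusted over the list alone (cameraPR adjusted p = 0.212).

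Markers of the adrenergic state of neuroblastoma were mixed and several mesenchymal markers fell. Among 24 measured adrenergic genes, 8 rose and 3 fell in the authors' deposited table by DESeq2 (9 and 3 when adjusted over the list alone), with a cameraPR adjusted p of 0.0925. MYCN rose by 1.09 (SE 0.16) and CHGB, a protein of secretory granules, by 0.89 (SE 0.16), while the transcription factor ISL1 was at -0.77 (SE 0.14) in the authors' deposited table. Of 16 measured mesenchymal genes, 5 fell and 1 rose in the authors' deposited table by DESeq2, also when adjusted over the list alone: VIM was at -1.54 (SE 0.14), IRF1 at -1.36 (SE 0.18), FN1 at -1.10 (SE 0.22) and SOX9 at 0.59 (SE 0.21). That list had a cameraPR adjusted p of 0.0108, and 0.0677 with a preset correlation of 0.05. Fibroblast and matrix markers had 5 of 14 members down and 0 up in the authors' deposited table by DESeq2, also when adjusted over the list alone, with COL6A2 at -1.34 and PDGFRB at -0.94 (cameraPR adjusted p = 0.055). Of 6 measured Schwann and glial markers S100B rose, at 1.21 in the authors' deposited table, also when adjusted over the list alone (cameraPR adjusted p = 0.353). Of 15 immune, epithelial, endothelial and blood markers, 1 was measured, EPCAM at -0.38 (SE 0.29, DESeq2 adjusted p = 0.331) in the authors' deposited table (cameraPR adjusted p = 0.686).

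Neuronal gene groups did not move as a block. The authors' deposited table had 10 of 31 neuronal cytoskeleton and axon genes up and 3 down by DESeq2 (11 and 3 when adjusted over the list alone), with the adhesion molecule CNTN1 at 1.17 (SE 0.15), the RNA-binding protein ELAVL2 at 1.21 (SE 0.20) and peripherin, PRPH, at -0.77 (SE 0.13). Synaptic vesicle and release genes had 5 of 29 up and 7 down in the authors' deposited table by DESeq2 (6 and 7 when adjusted over the list alone), with RAB3A at 0.95 and the vesicular acetylcholine transporter SLC18A3 at -0.93. Among 20 voltage-gated ion channel genes, 8 rose and 3 fell in the authors' deposited table by DESeq2, also when adjusted over the list alone; the sodium channel genes SCN8A, SCN2A and SCN3A were at 1.22, 1.27 and 0.98. The cameraPR adjusted p values of these lists were 0.161, 0.728 and 0.0719.

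**Figure D2:**
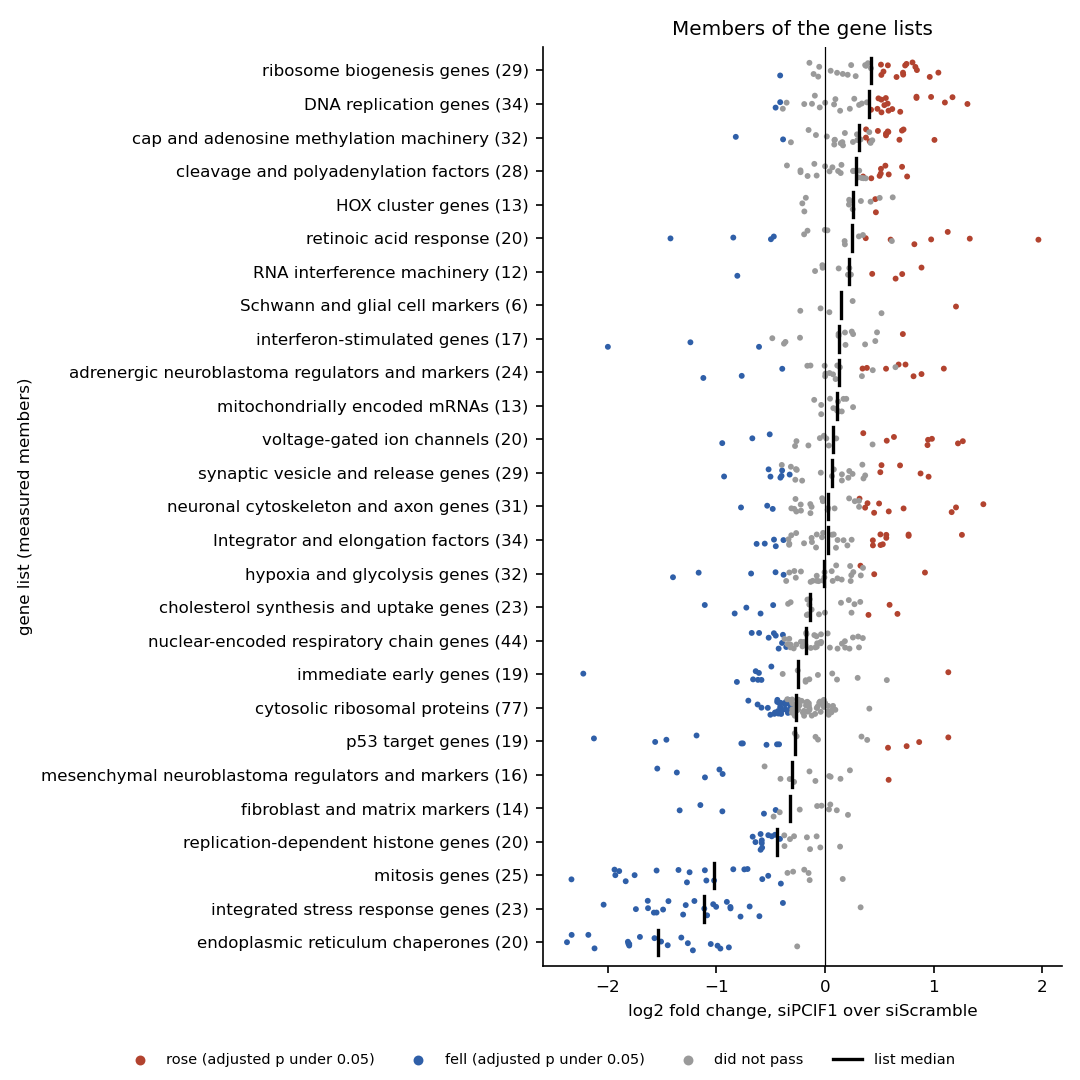
Log2 fold change, siPCIF1 over siScramble, of each measured member of 27 gene lists in the authors' deposited table (points; red rose, blue fell, grey did not pass; black line, list median), with the number of measured members in brackets. The chaperone, integrated stress response and mitosis lists lie lowest, with medians of -1.54, -1.11 and -1.02, and ribosome biogenesis genes lie highest at 0.42.

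Growth-signal and p53 target genes were lower on balance. Of 19 measured immediate early genes, 8 fell and 1 rose in the authors' deposited table by DESeq2, also when adjusted over the list alone, with MYC at -2.22, JUN at -0.81 (SE 0.15) and BTG2 at 1.13 (SE 0.18). The list had a cameraPR adjusted p of 0.0321, and 0.13 with a preset correlation of 0.05. With the trend of GC content, length and expression removed it was 0.331, and the median went from -0.25 to -0.05 in the authors' deposited table. Of 19 measured p53 targets, 9 fell and 4 rose in the authors' deposited table by DESeq2 (9 and 5 when adjusted over the list alone): TNFRSF10B was at -2.13, GDF15 at -1.56 (SE 0.16), the cell cycle inhibitor CDKN1A at -1.46 (SE 0.17), BTG2 at 1.13 and MDM2 at 0.58. TNFRSF10B and GDF15 are also known targets of the stress factors DDIT3 and ATF4. This list had a cameraPR adjusted p of 0.0139, 0.081 with a preset correlation of 0.05 and 0.164 by ranks.

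Metabolic and interferon lists did not pass as groups, with large changes of single members. Of 23 cholesterol genes 5 fell and 3 rose in the authors' deposited table by DESeq2, also when adjusted over the list alone, with MVD at -1.11 and HMGCS1 at 0.67 (cameraPR adjusted p = 0.403). Hypoxia and glycolysis genes had 5 of 32 down and 3 up in the authors' deposited table by DESeq2 (5 and 1 when adjusted over the list alone), with the collagen hydroxylase P4HA2 at -1.40 (cameraPR adjusted p = 0.563). Of 17 measured interferon-stimulated genes, 3 fell and 1 rose in the authors' deposited table by DESeq2, also when adjusted over the list alone, with ISG20 at -2.00 and IFIT5 at 0.72; the median was 0.12 while cameraPR, at an adjusted p of 0.544, pointed down. Nuclear-encoded respiratory chain genes had 9 of 44 down and 0 up in the authors' deposited table by DESeq2 (8 down when adjusted over the list alone), with a median of -0.17 that became 0.02 once the trend with GC content, length and expression was removed, and a cameraPR adjusted p of 0.129. Of the 13 mitochondrially encoded mRNAs, 0 passed by DESeq2 in the authors' deposited table, with a median of 0.11 (cameraPR adjusted p = 0.634).

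Zinc finger genes, taken as all symbols of ZNF and a number, rose more often than they fell. Of 425 measured, 121 rose and 31 fell in the authors' deposited table by DESeq2, also when adjusted over the list alone, with a median of 0.24. ZNF121 and ZNF195 were at 1.13 (SE 0.16) and 1.09 (SE 0.19), and ZNF853 and ZNF622 at -1.60 (SE 0.20) and -1.17 (SE 0.14) in the authors' deposited table. The cameraPR adjusted p was 0.000834, and 0.145 with a preset correlation of 0.05. With the trend of GC content, length and expression removed from the authors' deposited table, 49 passed as higher and 15 as lower, with a median of 0.13 and a cameraPR adjusted p of 0.0458.

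An inter-gene correlation could not be estimated from a table without values per library; at the preset 0.01, 13 of the 29 lists passed, and at 0.05 6 did, namely chaperones, integrated stress response, mitosis, DNA replication, ribosome biogenesis and histones. Against random lists matched on mean expression the adjusted p was 0.341 for cytosolic ribosomal proteins, 0.0575 for histones, 0.0563 for mesenchymal genes, 0.0995 for p53 targets and 0.119 for immediate early genes. With the trend of GC content, length and expression removed, histones (cameraPR adjusted p = 0.464), ribosomal proteins (0.788) and immediate early genes (0.331) no longer passed. The adrenergic (0.000334), retinoic acid (0.000636), neuronal cytoskeleton (0.0257) and HOX lists (0.0382) then passed as higher. Their medians in the authors' deposited table, with the trend removed, were 0.41, 0.38, 0.20 and 0.41. The fibroblast list (0.0257) passed as lower, with a median of -0.40. The same removal left 5 cleavage and polyadenylation factors (median 0.20) and 6 cap and adenosine methylation genes (median 0.20) passing as higher, and 4 immediate early genes (median -0.05) as lower, in the authors' deposited table. Among genes without TCAAGT, with fewer members, cleavage and polyadenylation factors (8 members, median 0.11 in the authors' deposited table) and mesenchymal genes (4 members, median -0.07) did not pass, with cameraPR adjusted p of 0.419 and 0.628. By ranks, cameraPR gave 0.164 for p53 targets, 0.0404 for the respiratory chain and 0.0448 for fibroblast markers, and among genes with a mean of at least 100 ion channel genes had 0.0112.

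The series title concerns full-length transcription, so fold changes were compared with gene length. Long genes were higher relative to short ones with siPCIF1. Among 8797 genes with a mean of at least 100 in 5 equal bins, those of the shortest bin, up to 10.7 kb long, lay lowest; their median log2 fold change in the authors' deposited table was -0.23 (95% bootstrap interval -0.25 to -0.20), with 621 of 1760 genes down and 127 up. In the bin of the longest genes, from 102 kb up, it was 0.20 (0.18 to 0.21) in the authors' deposited table, with 161 of 1760 genes down and 547 up. Spearman's correlation across genes was 0.337 with genomic length (permutation p = 1e-05, the smallest that 100000 permutations give); genes are not independent replicates. GC content of the main transcript had the stronger relation, at -0.479, with medians in the authors' deposited table from 0.34 in the bin lowest in GC to -0.29 in the highest. By DESeq2, 770 of 1760 genes rose and 124 fell in the lowest GC bin, and 49 of 1760 rose and 693 fell in the highest. Given GC content and mean expression the correlation with length was 0.197, and given transcript length as well it was 0.0996, so the size of the length relation moved more than 1.5-fold with these terms.

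**Figure D3:**
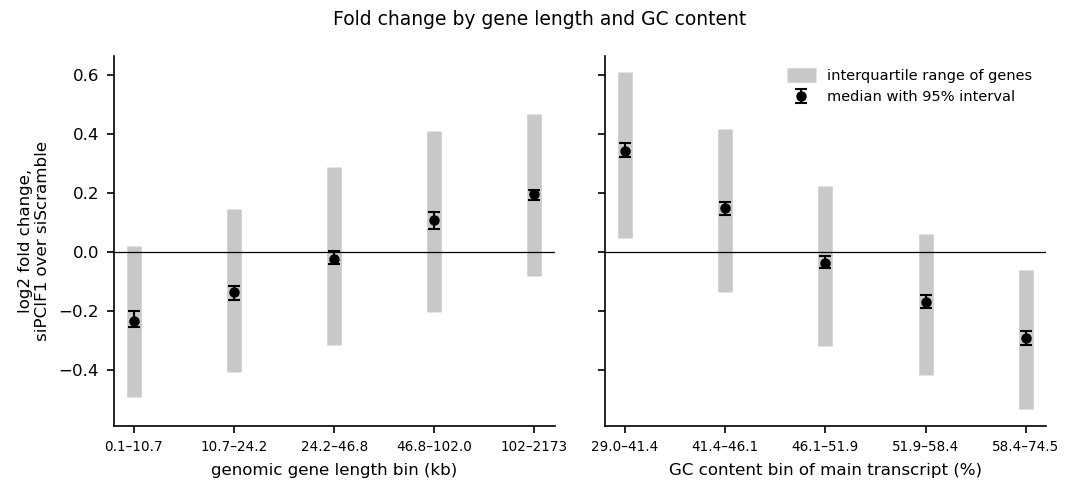
Log2 fold change, siPCIF1 over siScramble, in the authors' deposited table for 8797 genes in 5 equal bins of genomic length (kb, left) and of GC content of the main transcript (percent, right); points are medians with 95% bootstrap intervals and grey bars the interquartile range of genes. Medians rise from -0.23 to 0.20 with length and go from 0.34 to -0.29 with GC content.

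PCIF1 methylates transcripts whose first base is adenosine, so genes were also divided by that base. Genes whose annotated main transcript starts with A had a median log2 fold change of -0.02 (2491 genes) and the others one of -0.02 (6306 genes) in the authors' deposited table. The difference was -0.0015 (95% bootstrap interval -0.025 to 0.030, two-sided permutation p = 0.91). No difference was therefore detected with annotated starts, and the interval holds only small shifts in either direction. By the share of a gene's annotated starts that are A, Spearman's correlation across genes was 0.0894 (permutation p = 1e-05, the smallest possible), and 0.021 given GC content, gene length, transcript length and mean expression.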

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

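No paired analysis was possible because the table holds no values per library; for the same reason leaving out each replicate, count models and splits of the samples were not run, and the depth of single libraries sets no stated limit. The trend-removed, TCAAGT-free, partial-correlation and unshrunken alternatives were chosen after the data were seen. Of 48 alternative values for the main results 36 kept their side of the threshold (counts, a size within 1.5 times) and, where called, their direction, as did 122 of 125 for named genes and 141 of 167 for single lists. All but PCF11 of the named genes counted here were chosen as the largest passing changes, so their tally was largely set by that choice. An adjustment over every gene repeats the deposited one, so its values among the 48 could not differ. The unshrunken value of PCIF1 keeps the deposited Wald statistic and adjusted p, so it could not change side either. The number of changed genes was 731 with an absolute log2 change of at least 1, 1526 tested against 0.3, 135 with the empirical null and 1999 of the 6439 genes without TCAAGT, each by a stricter rule or fewer genes. It was 3485 with the trend with GC content, length and expression removed. The share of changed genes that fell was 51.2% at a threshold of 0.1 and 50.8% after the trend was removed, where its interval took in equal shares. It turned to 47.9% after centring, which shifts every fold change upward by the same amount and so moves this balance by construction. The share was 62.7% among genes without TCAAGT, which were not matched on length or GC content, and 52.0 to 84.4% over the remaining alternatives. PCIF1, at -0.82, did not pass with the empirical null (adjusted p = 0.747, against 0.000127 to 0.0329 over its other alternatives). The lists called numbered 6 with a correlation of 0.05 and 8 against random lists, and zinc finger genes had an adjusted p of 0.145 with the former. The direction turned for cytosolic ribosomal proteins after the trend was removed (cameraPR adjusted p = 0.788) and for immediate early genes among those without TCAAGT (0.866); the cause was not tested. First bases had no called direction at -0.0015 (p = 0.91); as a share of starts, on another scale, Spearman's correlation was 0.0894 (permutation p = 1e-05), and 0.021 given the covariates.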

Other observations

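The tests of base composition of the 3′ UTR and of the word in PCIF1 were chosen after the results were seen. The other tests had bounds written before they were run. The words TCAAGTA and ATCAAGT came from the scan of the same 8052 genes. The order of the site types and the smaller shift upstream of the 3′ UTR are therefore not independent of that choice. The 7 stress regulators given next were picked after their values were seen, so they stand for no group. The authors' deposited table gave the endoplasmic reticulum stress sensors ERN1, ATF6 and EIF2AK3 log2 fold changes of -0.86 (SE 0.18), -0.66 (SE 0.15) and -0.58 (SE 0.16), each past a DESeq2 adjusted p of 0.05. XBP1, the transcription factor activated by ERN1, was at -1.32 (SE 0.16), CREB3L2 at -0.93 (SE 0.15) and PPP1R15A, the phosphatase subunit that restores translation after stress, at -1.72 (SE 0.16) in the authors' deposited table, whereas ATF6B was at -0.12 (SE 0.18). The G1 cyclin gene CCND1 was at 1.14 (SE 0.14) in the authors' deposited table, opposite to the mitotic cyclins.

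RNAs without a long poly(A) tail took up a large part of the counts of these poly(A)-selected libraries, and in each class below more members fell than rose, with no test of the classes. In the authors' deposited table, the mitochondrial rRNA MT-RNR2 made up 34.0% of the summed mean normalised counts and RN7SL2, the RNA of the signal recognition particle, 11.6%; the latter has near-identical copies and its value is uncertain. Of 68 small nucleolar RNAs 29 fell and 1 rose, of 25 RNAs of the 7SL, 7SK, Y and vault families and their copies 16 fell and 0 rose, and of 8 Cajal body RNAs 5 fell and 0 rose, by DESeq2 in the authors' deposited table. Their medians in the authors' deposited table were -0.47, -0.47 and -0.59, both mitochondrial rRNAs fell, though their median turned to 0.11 with the trend of GC content, length and expression removed, and small nuclear RNAs had a median of -0.11 (upper quartile 0.32) with 11 of 40 down and 1 up. With that trend removed, the medians of small nucleolar RNAs, the 7SL, 7SK, Y and vault families and Cajal body RNAs in the authors' deposited table were -0.21, -0.15 and -0.19. BCYRN1, a neuronal small RNA, was at -1.17 (SE 0.14) in the authors' deposited table. Short protein-coding transcripts, under 700 bases, had a median of -0.26 in the authors' deposited table, which turned to 0.06 with the trend removed.

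A sequence word marked genes that were lower with siPCIF1 once covariates were included: among 16050 words of 7 bases, TCAAGTA and ATCAAGT in the 3′ UTR had the lowest coefficients relative to their SE, and the shift was -0.28 (SE 0.032) for the 208 genes with ATCAAGTA, -0.12 and -0.11 for either 7-base part and -0.05 for TCAAGT. Without covariates the sign was opposite, with medians in the authors' deposited table of 0.05, 0.12 and 0.12 for ATCAAGTA, TCAAGTA and ATCAAGT and of -0.07 with no site, and more genes of either 7-base class rose (28.2% and 29.4%) than fell (16.2% and 15.9%) by DESeq2. At the other end of the scan, TGCATTG had the highest coefficient relative to its SE, at 0.066 (SE 0.015) in 1183 genes. It also passed, with an adjusted p from the linear regression of 0.0396, and its cause was not tested. Base composition alone is argued against by a test with the genes split at random, once, into 2 sets of 4026: TCAAGTA had the lowest coefficient relative to its SE in each set and then ranked 1 among 412 and 410 words of its bases in the other (within the lowest 0.244%), which replaced a rank of ATCAAGTA taken on the genes it was chosen from; sites upstream of the 3′ UTR had a smaller shift of -0.0609 (SE 0.016). A candidate explanation is pairing of the seed of an siRNA strand with these 3′ UTRs: the main transcript of PCIF1 holds ATCAAGT 1 time, at base 1196 of 2747, as do 13.0% of transcripts of like length. With 1 siRNA per group, and its sequence not given in the sources used here, that stays a hypothesis.

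The joint decrease of the chaperone, integrated stress response and mitosis lists was set against that hypothesis. Of their 68 members 33 lack TCAAGT in the main transcript, and these had a median of -1.55 in the authors' deposited table, so sites in the members' own mRNAs do not account for it. Nor does the trend with GC content, length and expression, after whose removal the median of the 68 was -1.11. An effect of PCIF1 loss remains open as a hypothesis, and so does one through a regulator that carries a site, such as XBP1 or CREB3L2, whose 3′ UTRs hold TCAAGTA. HMOX1 holds it too, as does VLDLR, which did not fall. Of the 1297 genes with TCAAGTA or ATCAAGT in the 3′ UTR, 221 fell in the authors' deposited table by DESeq2, against 1675 of all 8052 genes. A second siRNA against PCIF1, or its rescue, was not analysed here. A difference that arose in the siScramble samples, or between cultures, would give the same contrast and cannot be told apart here.

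Long genes were higher relative to short ones with siPCIF1; where transcripts ended was not analysed here. Whether GC content of the transcript is the whole cause was not decided. Given GC content and mean, a correlation of 0.197 remained (95% interval 0.176 to 0.217). That lies above the bound of 0.1 set for this cause but below the 0.2 set as excluding it. Given transcript length as well, 0.0996 remained (0.0783 to 0.121), and the interval straddles the bound, so a length-dependent effect on the transcripts, through fragmentation or RNA integrity, cannot be told apart from one on genomic length. A biological difference between the groups stays open and untested.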
